A study of Mus musculus with 14 samples.

How the data were processed

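RNA of B16F10 tumours grown in C57BL/6 mice was hybridised to Agilent one-colour (Cy3) whole mouse genome arrays, 14 in all, on 4 slides. Per the labels, total RNA was extracted with TRIzol and the RNA of 3 or 4 tumours was pooled for each array. Each arm has 1 array per day, so no combination of arm and day is replicated. Scanned images were quantified with Agilent Feature Extraction 9.5, per the submitters' processing notes, and the file headers give version 9.5.3.1. The deposited scanner files hold spot intensity on a linear scale, and the processed signal used here is background-subtracted and corrected by that program, per the file headers. The authors also deposited a table of log2 values for the same arrays. Set against the log2 processed signal of the same array, each of its columns correlated at r = 1 over 41174 probes and differed from it only by a constant per array. That constant places the 75th percentile of each column at about 0, with column medians from -3.54 to -3.14. Scale, centring and direction of the authors' table were thereby settled from the values.

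From the scanner files, the log2 of the processed signal was taken and the 75th percentile of the array's 43379 non-control spots was subtracted. Spots of one probe were averaged. Spots marked as outliers were left out, which left 29 probes without a value on at least 1 array. A probe was kept where it was well above background on at least 3 arrays. One probe per gene was used, the one with the highest mean over all arrays, which gave 17031 genes. Of 41174 probes, 24375 were named through an accession in the gene table given with the data, which changed the name of 4783, and 16799 kept the name in the file. Probe coordinates are those of the files, in build mm8. No reference genome or exon annotation was used here.

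Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with arm and day as terms, Benjamini-Hochberg adjustment over all genes and a two-sided threshold of 0.05. The day is given by the labels and equals the slide, so the day term is also the slide block and each same-day difference is a difference within a slide. Array position on the slide was the same for each arm on every slide, so position and arm cannot be told apart. Errors are standard errors, and n counts days. The p-values measure how much same-day differences of pooled tumours vary from day to day, and say nothing of the spread between single mice. As a check of the pairing over days 3, 5 and 7, arrays of the same day deviated from their arm means with a median r of 0.129 across genes. Arrays of different days had -0.0548, but centring each arm on its mean pushes these to the opposite sign, so they are no comparator. CTL with untreated arrays had r of 0.146, -0.0231 and 0.0692 on days 3, 5 and 7, so the check says little for that pairing. Antibody with IgG arrays had 0.0941, 0.256 and 0.172, and the highest r was that of CTL with IgG arrays on day 3. Of 18 same-day pairs, 12 had r over 0.1, with a range from -0.0442 to 0.510.

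CTL against untreated tumours and anti-interferon gamma against IgG were fitted on all 14 arrays. IgG with CTLs against CTLs alone, and the antibody with CTLs against untreated tumours, were fitted on the 12 arrays of days 3, 5 and 7. An interaction term compared the CTL effect of days 3, 5 and 7 with that of day 1, and a slope term was fitted over days 3, 5 and 7. Before the data were examined, the comparisons, 27 gene lists, the alternatives and a rule for the genes named were fixed. The rule took the 10 highest and 10 lowest log2 changes (5 and 5 for the secondary comparisons) among genes with an ordinary symbol that passed the threshold, kept 1 sign on every day and were well above background on every array of at least 1 of the arms compared. For the interaction term it was applied to the CTL and untreated arrays. After the values were seen, an error in the pattern that tells symbols from accessions was corrected, which had left out symbols such as H2-Aa and C5ar1. The rule added the 2 to 4 members with the smallest p of each list described, and 21 genes chosen for the biology of the study. Of these 21, Nos2 did not pass the filter on dim probes. Leaving out each day in turn was among the alternatives fixed then. Naming antibody genes from the fit without day 1 was decided only after the fit of all 14 arrays had given 2 genes.

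Lists were tested with camera at a preset correlation of 0.01, with camera at a correlation estimated from the data (statmod 1.5.0) and with fry, each adjusted over 27 lists. For a single day, the median of a list was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Where a probe was not well above background on any array of an arm, the difference is a bound, given as "at least N-fold". It sets the mean of the bright arm against, per array, the higher of the lowest signal well above background and the probe's own signal.

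The scripts were tested on data in which genes were changed by a simulated amount. At a simulated log2 size of 1, 2 and 4, CTL against untreated recovered 80.6%, 91.0% and 92.4% of changed genes, and anti-interferon gamma against IgG 62.7%, 91.0% and 97.0%. The interaction term recovered 10.4%, 43.3% and 75.8%. Of the genes called, 5.38%, 5.65% and 2.27% in turn were false. In the first 2 comparisons the simulated change was the same on every day, and the noise was independent between genes. Real members of the interferon gamma list had a median residual SD of 1.14 in the fit of all 14 arrays, against 0.219 over all genes. The shares recovered therefore do not apply to genes that vary as much between days. The alternatives tried were quantile normalization, normexp background correction (offset 50) with quantile normalization, the authors' values, no filter or a filter on all 14 arrays, other rules for probes, eBayes with trend and robust, only the arrays of the arms compared, no day term, and leaving out each day or array. Figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision of every value.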

Results

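Gene expression was measured in tumours of B16F10, a melanoma line of C57BL/6 mice, during adoptive T cell therapy. Tumour-bearing mice received cytotoxic T lymphocytes (CTLs) that had been activated in culture and recognise gp100, the melanocyte protein encoded by Pmel. Untreated and CTL arms have 4 arrays each, from days 1, 3, 5 and 7 after transfer, each with RNA of 4 tumours. In 2 further arms CTLs were given with a blocking antibody against interferon gamma or with a control rat IgG. Each of these has 3 arrays, from days 3, 5 and 7, with RNA of 3 tumours per array. Between 48.9% and 59.7% of the spots of an array were well above background, and the 75th percentile of the processed signal ranged from 301 to 536. The first principal component held 49.4% of the variance. CTL and IgG tumours of days 3, 5 and 7 lay between 28.8 and 72.9 on it, and the remaining arrays between -54.2 and -21.9, including CTL day 1 at -38.3.

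**Figure D1:**
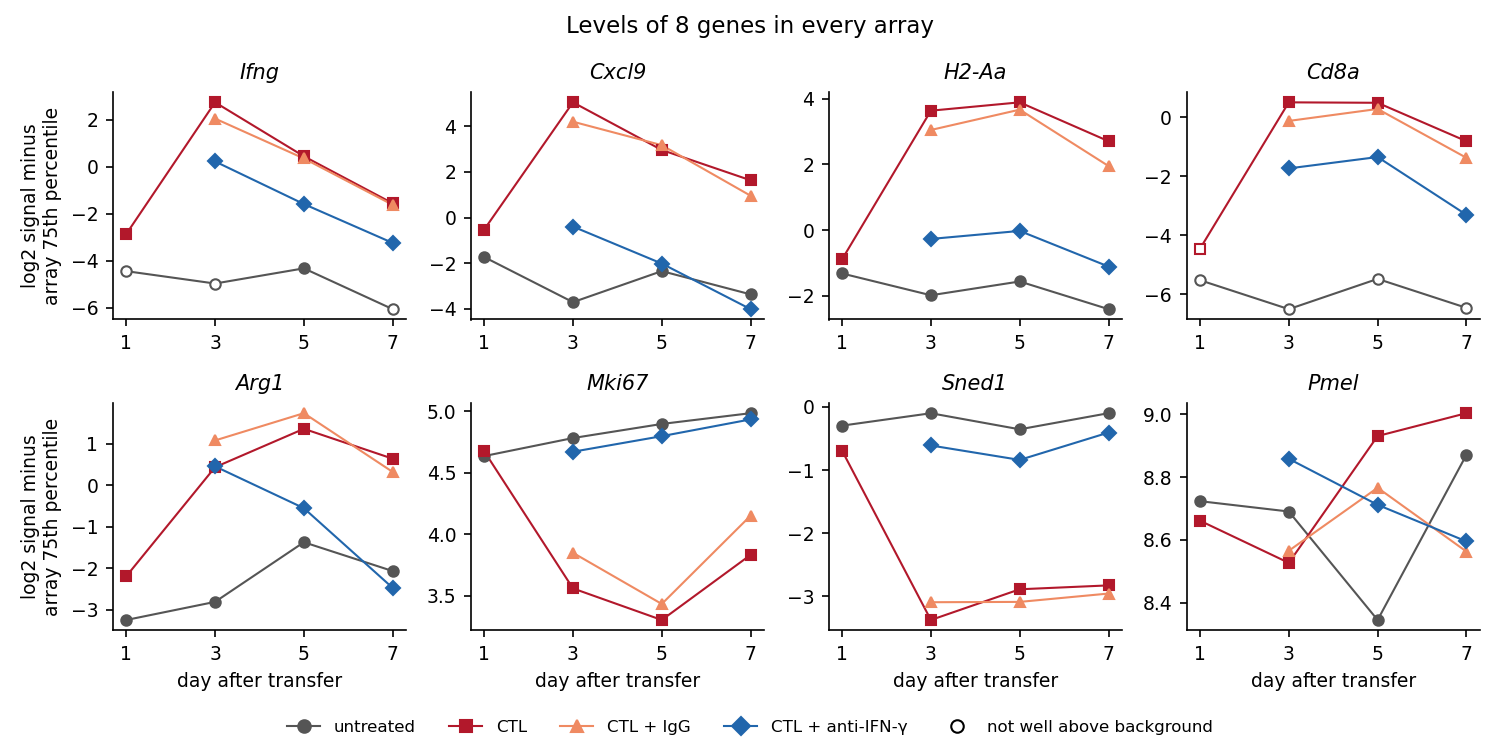
Levels of 8 genes on every array, as log2 signal minus the array's 75th percentile, against the day after transfer, with 1 point per array and a line per arm. Open points were not well above background; Cd8a was below that limit on all 4 untreated arrays, and H2-Aa with CTLs and anti-interferon gamma lay between the untreated and the IgG arrays on each day.

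The first comparison asked what CTL transfer changed in the tumour. Genes induced by interferon gamma, antigen presentation genes and genes of T cells and macrophages rose, and some genes of cell division and of blood vessels fell. Ubd, a ubiquitin-like protein induced by interferon gamma, rose by a log2 change of 6.45 ± 1.15 (SE, n = 4 days). It was not well above background on any untreated array, which makes the rise at least 37.5-fold. Cxcl9, a chemokine that attracts activated T cells, rose by 5.07 ± 0.95, or 33.6-fold. Sned1, a protein of the extracellular matrix, fell by 2.23 ± 0.37. Ubd was measured at chromosome 17, 36803796 to 36803855, Cxcl9 at chromosome 5, 93398365 to 93398424, and Sned1 at chromosome 1, 95131270 to 95131329 (mm8).

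The interferon gamma list had 21 of 25 measured members higher and none lower over all genes tested, and 23 when adjusted over the list alone. Its median log2 change was 3.56. Among the genes with the largest changes were the guanylate-binding proteins Gbp4 (6.12 ± 1.08) and Gbp6 (6.09 ± 1.14), the immunity-related GTPases Iigp1 (5.02 ± 0.94) and Tgtp1 (4.91 ± 0.80), Apol6 (5.69 ± 1.14), the nucleic acid sensor Zbp1 (5.00 ± 1.08), Slamf8 (4.91 ± 0.74) and Irg1, the enzyme that makes itaconate (4.90 ± 0.91). The transcription factor Irf1 rose by 3.16 ± 0.58. Cxcl10 had 1.56 ± 0.71 and did not pass (limma, adjusted p = 0.141). Of the type I interferon list 15 of 22 rose (21 adjusted over the list alone), with Rtp4 at 2.88 and Oasl2 at 4.02. In antigen presentation, 19 of 22 class I genes rose (19 adjusted over the list alone), among them the immunoproteasome subunits Psmb8 (4.08) and Psmb9 (4.11) and the peptide transporter Tap1 (3.18). Of the class II genes 9 of 10 rose (10 adjusted over the list alone), among them the transactivator Ciita (4.85) and H2-Aa (4.15 ± 0.72). For the interferon gamma, class I and class II lists the camera call was lost (adjusted p = 0.171 with an estimated correlation), as it was for the type I list (adjusted p = 0.188 with an estimated correlation).

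Lymphocyte genes rose with them. Of the cytotoxic effector list 11 of 13 rose (11 adjusted over the list alone; adjusted p = 0.171 with an estimated correlation), with a median of 3.69, or 2.71 with dim members at their bound. Ifng rose by 4.64 ± 0.74 and Gzmb, encoding granzyme B, by 4.71 ± 1.04. Of the T cell list 11 of 22 rose and 1 fell (15 and 2 adjusted over the list alone; adjusted p = 0.188 with an estimated correlation). Cd8a, the CD8 alpha chain, was at least 9.62-fold higher, well above background on 3 of 4 CTL arrays and on no untreated array. The member that fell, Cd8b1, named after its value was seen, has 2 probes that moved in opposite directions. Of the list of inhibitory genes 3 of 9 rose (7 adjusted over the list alone), namely Havcr2 (1.26), Pdcd1 (2.19) and Cd274, which encodes PD-L1 (2.07 ± 0.56). Of the natural killer list 3 of 5 rose (4 adjusted over the list alone), with Klra8 at least 1.95-fold higher, and both lists lost their call (adjusted p = 0.171 with an estimated correlation). Of the B cell list 2 of 7 rose, Cd22 (0.64) and Blnk (1.38) (2 adjusted over the list alone; adjusted p = 0.198 with an estimated correlation). Thy1, whose CD90.1 form marks the transferred cells, had 1.38 ± 0.39 (adjusted p = 0.0531).

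Of the monocyte and macrophage list 16 of 22 rose and 1, Chil3, fell (20 and 1 adjusted over the list alone). The Fc receptors Fcgr4 and Fcgr1 rose by 3.07 and 2.70, and Ccr2, the receptor of Ccl2, was at least 3.38-fold higher. Of the list of myeloid suppressor genes 8 of 15 rose (12 higher and 1 lower adjusted over the list alone), among them Arg1, encoding arginase 1 (2.44 ± 0.55), and Il4ra (1.37). Of the dendritic cell list 5 of 12 rose (6 higher and 1 lower adjusted over the list alone), with Itgax at 1.80. Of the chemokines 12 of 27 rose and 1, Ccl27a, fell (13 and 3 adjusted over the list alone), with Cxcl16 at 3.06 and Ccl2 at 1.57 ± 0.35. These 4 lists lost their call (adjusted p = 0.171 with an estimated correlation). Of the neutrophil list 3 of 10 rose (5 adjusted over the list alone; adjusted p = 0.207 with an estimated correlation), with Csf3r at 1.99, and S100a8 had 1.71 ± 0.89 without passing. Of the cell death list 10 of 23 rose (15 adjusted over the list alone; adjusted p = 0.203 with an estimated correlation), with the caspases Casp1 at 2.53 and Casp12 at 3.91.

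Among proliferation genes, 7 of 34 G2/M genes fell and none rose (31 adjusted over the list alone; adjusted p = 0.329 with an estimated correlation), with a list median of -0.63. Mki67, the Ki-67 antigen, fell by 0.98 ± 0.23, and Ccnb1 had -0.84 ± 0.26 without passing. Of the G1/S list 2 of 32 fell, Orc1 (-0.88) and Rrm1 (-0.69) (22 adjusted over the list alone; adjusted p = 0.367 with an estimated correlation). Of the cell cycle inhibitors 2 of 18 rose, Gadd45b (1.44) and Btg1 (0.92) (4 higher and 1 lower adjusted over the list alone; adjusted p = 0.329 with an estimated correlation), while Cdkn1a had -0.30 ± 0.16. Of the endothelial list 4 of 16 fell (6 adjusted over the list alone), Cldn5 (-0.96), Emcn (-1.03), Egfl7 (-0.52) and Robo4 (-0.80), and camera made no call (adjusted p = 0.0596). Other genes that fell were Plekhg4 (-2.02), the lipid transporter Abca12 (-1.80), Rbp7 (-1.76), the metalloproteases Adam12 (-1.74) and Adamts20 (-1.61), Mgam (-1.72), Prkar1b (-1.61) and Esm1 (-1.60). Of the melanocyte list Cited1 rose (1.24) and Kit fell (-0.87) among 20 (1 and 1 adjusted over the list alone), with a median of 0.04. Pmel had 0.12 ± 0.15, Tyr -0.51 ± 0.23, and the interferon gamma receptor genes Ifngr1 and Ifngr2 -0.24 ± 0.11 and 0.07 ± 0.13.

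Few markers of tissues that can be dissected with a tumour passed. Of the erythroid list 1 of 7 fell, the haemoglobin gene Hba-a1 (-2.22 ± 0.61) (4 adjusted over the list alone; adjusted p = 0.416 with an estimated correlation). Of the keratinocyte list 2 of 8 rose, Krt14 (1.15) and Krt5 (0.85) (3 adjusted over the list alone; adjusted p = 0.171 with an estimated correlation). Fn1, encoding fibronectin, rose by 1.00 as the only member of the 18 fibroblast genes to pass (1 adjusted over the list alone). No gene of the 13 skeletal muscle or 8 adipocyte genes passed (limma; 0 and 0 adjusted over the list alone), with Lpl at 0.89 (adjusted p = 0.0760); the adipocyte call was lost (adjusted p = 0.246 with an estimated correlation). Ankrd37 fell among 19 hypoxia and glycolysis genes (-1.01; 5 adjusted over the list alone) and Gusb among 14 housekeeping genes (-0.60; 4 adjusted over the list alone).

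In all, 1837 of 17031 genes passed, 828 higher and 1009 lower, at adjusted p values of 0.00247 or more, and the median change of all genes was -0.08. Camera called 21 of 27 lists, 18 higher and 3 lower, fry called 19, and 0 remained with an estimated correlation. The lists fry called include the housekeeping list as lower (fry, adjusted p = 0.0147), which camera did not call (adjusted p = 0.271). That correlation comes from the residuals of a fit with 1 CTL effect for all days. For class II genes it was 0.852 with day 1 and 0.344 without, and for interferon gamma genes 0.859 and 0.806. Without day 1 the lowest adjusted p of camera with an estimated correlation was 0.0679, so 0 lists were called there too. The count of genes rose to 5363 (1722 higher, 3641 lower) without day 1 and was 0 without day 3, day 5 or day 7. It was 5 without the day term and 1 with only the 8 arrays of these arms.

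**Figure D2:**
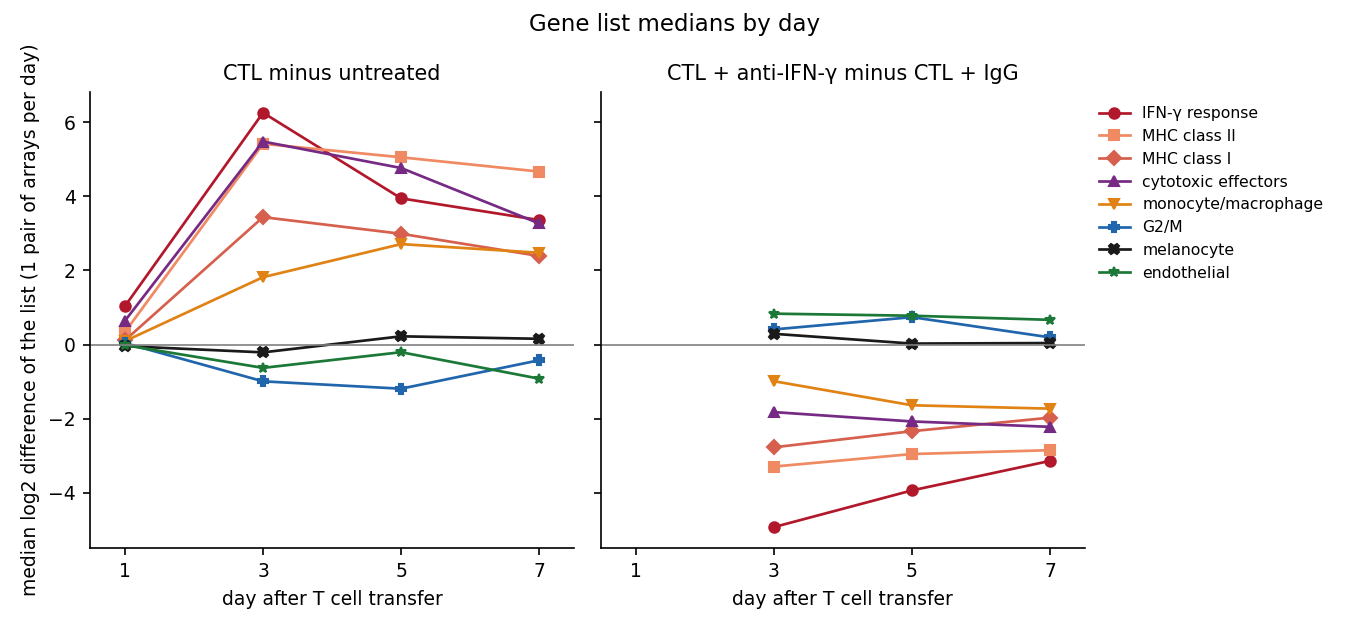
Median log2 difference of 8 gene lists on each day, CTL minus untreated at left and CTL with anti-interferon gamma minus CTL with IgG at right; each point is 1 array against 1. The interferon gamma list stood at 1.04 on day 1 and 6.26 on day 3 with CTLs, and at -4.93 on day 3 with the antibody.

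The time course asked when the CTL effect was present. On day 1 the difference between CTL and untreated tumours was smaller than later. The interferon gamma list had a median of 1.04, against 6.26 on day 3, 3.95 on day 5 and 3.36 on day 7. All 25 measured members of that list were already above 0 on day 1. Each of these 4 medians lay at percentile 100 of matched random lists, which do not carry the correlation between the list's genes. Class II genes had 0.34 on day 1 and 5.42, 5.06 and 4.67 later, and G2/M genes 0.04 and then -0.99, -1.19 and -0.42. The interaction term was past the threshold for 173 genes, 142 with a higher effect on days 3, 5 and 7 than on day 1 and 31 with a lower one. Cd3d, a chain of the T cell receptor complex, differed by 6.09 ± 1.06, Apol9b by 5.30 ± 0.93, and the class II genes H2-Aa and H2-DMb1 by 4.96 ± 0.32 and 4.94 ± 0.50. The fitted differences of Ubd (7.16 ± 1.25) and Cd8a (5.15 ± 0.56) rest on untreated arrays that were all below the background limit. On the lower side were Sned1 (-2.45 ± 0.30), Khdrbs3, an RNA-binding protein (-1.93), Sox21 (-1.72), Ica1l (-1.70) and Gxylt1, a glycosyltransferase (-1.40). With all probes of a gene averaged, Sox21 and Cd8a no longer passed (-0.60 and 3.79). No gene had a slope over days 3, 5 and 7 that passed limma's test. An unadjusted p under the threshold was found for 707 of 17031 genes, less than the share of 0.05 that chance alone would give. Day 1 is 1 pair of arrays and was assumed to vary like the other days. The count of genes with a CTL effect on days 3 to 7 minus day 1 was 5 without day 3, 4 without day 5 and 295 without day 7.

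The antibody comparison asked which genes differed when interferon gamma was blocked in mice given CTLs. In the fit of all 14 arrays the changes were large but missed the threshold over all genes. The 25 measured members of the interferon gamma list were all lower on each of the 3 days, with a median of -4.04, and all 25 passed when adjusted over the list alone. Cxcl9 had -4.92 ± 1.09 (SE, n = 3 days; limma, adjusted p = 0.0552) and Irf1 -3.62 ± 0.67. Mki67 had 0.99 ± 0.26 (adjusted p = 0.0658). Over all genes 2 transcripts passed, 1 higher and 1 lower, neither with an ordinary gene symbol, and 4520 genes had an unadjusted p under the threshold.

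Adjusted over the list alone, 19 of 22 class I genes were lower and 3 higher, 9 of 10 class II genes lower, and 21 of 22 type I interferon genes lower, with medians of -2.29, -2.94 and -3.23. The interferon gamma, class I, class II and type I calls of camera were lost (adjusted p = 0.206 with an estimated correlation). By the same measure 15 of 22 monocyte and macrophage genes were lower and 1 higher, 12 of 15 myeloid suppressor genes lower, 15 of 27 chemokines lower and 1 higher, and 16 of 23 cell death genes lower (adjusted p = 0.206 with an estimated correlation for each). No member of any of the 27 lists passed in limma over all genes, the lymphocyte and neutrophil lists included. Adjusted over the list alone, 9 of 22 T cell genes were lower and 2 higher (median -1.23; adjusted p = 0.296 with an estimated correlation), and 4 of 13 cytotoxic genes lower (median -2.01; adjusted p = 0.271 with an estimated correlation), and fry called neither list. Of the natural killer genes 4 of 5 were lower (median -2.48, or -0.29 with dim members at their bound), and of the neutrophil genes 7 of 10 (median -2.60, or -1.90 at the bound), each with adjusted p = 0.206 with an estimated correlation. Of the endothelial genes 10 of 16 were higher than with IgG (adjusted p = 0.232 with an estimated correlation), with a median of 0.86. The G2/M median was 0.46 and that of G1/S genes 0.40, with 0 members passing in limma over either list alone (adjusted p = 0.408 and 0.473 with an estimated correlation). The skeletal muscle median was -1.08, or -0.53 with dim members at their bound, with 11 of 13 members below 0 and 0 passing in limma over the list alone. The adipocyte median was -0.53, or -0.33 at the bound, with 2 genes lower adjusted over the list alone. Both calls were lost (adjusted p = 0.405 and 0.271 with an estimated correlation). The melanocyte median was 0.08. Camera called 21 lists, 3 higher and 18 lower, fry called 14, and 0 remained with an estimated correlation.

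Without day 1, which has no array of either arm and enters only through the shared estimate of the spread, 2136 genes passed, 1126 higher and 1010 lower. The genes from here to the end of the paragraph were named from that fit, which was chosen after the 2 genes above were seen. Gbp6 fell by 7.15 ± 0.90 (n = 3 days). The GTPase Tgtp1 also fell, as did Gbp4 (-7.11), Apol6 (-6.99), Iigp1 (-6.27), Zbp1 (-6.23), Ubd (-6.02) and the intermediate filament gene Prph (-5.55). Gbp8 was at least 16.5-fold and the interferon gene Ifi44 at least 17.8-fold lower, since neither was well above background with the antibody. The class II genes H2-Ab1 and H2-Aa had -2.86 ± 0.09 and -3.35 ± 0.16, Cd274 -2.77 and Cd8a -1.73, and all 4 fell. Ifng had -1.79 ± 0.56 and Gzmb -2.60 ± 0.77, which did not pass. Among genes that rose, the protocadherin Pcdh12 was at least 2.67-fold and the metalloprotease Mmp15 at least 1.92-fold higher. The complement receptor C5ar1 rose by 2.83 ± 0.57, Tenm4 by 2.47 ± 0.19, Sned1 by 2.43 ± 0.15, the water channel Aqp1 by 2.19, Esm1 by 2.15 and Igfbp3 by 2.15, while Foxo3 and the ephrin Efnb2 were each at least 1.25-fold higher. Of the lists, 22 of 25 interferon gamma genes and 9 of 10 class II genes fell, and 5 of 34 G2/M genes rose, among them Mki67. Of the endothelial genes 8 of 16 rose, with Kdr, the VEGF receptor, at least 2.37-fold higher and Emcn at 1.05. The camera calls of these 4 lists were lost in this fit too (adjusted p = 0.119 for interferon gamma, 0.0995 for class II, 0.360 for G2/M and 0.232 for endothelial genes, all with an estimated correlation). In the same fit 10 of 22 T cell genes fell and 2 rose. Of the cytotoxic genes 7 of 13 fell, of the natural killer genes 4 of 5 and of the neutrophil genes 5 of 10. Fry called the T cell and cytotoxic lists lower (adjusted p = 0.0292 and 0.0118), but also the housekeeping list higher (adjusted p = 0.00575). Camera with an estimated correlation called none of these lists (adjusted p = 0.216, 0.154, 0.119 and 0.155 in turn). The count of anti-IFNg versus IgG, without day 1, was 398 with day 3 also left out, 50 with day 5 and 1376 with day 7.

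**Figure D3:**
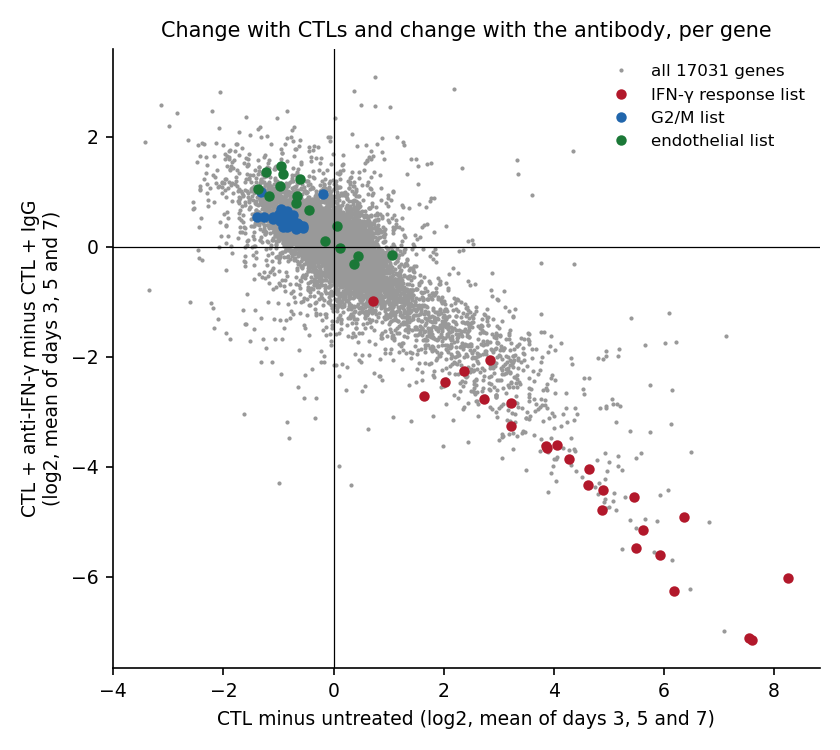
Each of 17031 genes by its CTL minus untreated difference (x axis) and its difference between CTL with anti-interferon gamma and CTL with IgG (y axis), both log2 and means of days 3, 5 and 7. Members of 3 lists are coloured; the correlation across genes was -0.79, and the interferon gamma genes lie at the lower right.

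A further question was whether the genes that differed with CTLs also differed with the antibody. The 2 contrasts share no array. Over days 3, 5 and 7 their log2 differences correlated across 17031 genes at r = -0.79 (rho = -0.69), with a slope of -0.64; genes are not independent replicates. Of the 828 genes that rose with CTLs, 792 were lower with the antibody on all 3 days, or 95.7% against 23.7% of all genes. Of the 1009 that fell, 921 were higher with the antibody on all 3 days, or 91.3% against 33.2% of all genes. In the fits of all 14 arrays the overlap of called genes was 0, since only 2 genes were called with the antibody. Without day 1, 898 of 1722 genes that rose with CTLs fell with the antibody, where independent lists would share 102. Of 3641 that fell with CTLs 931 rose with the antibody, where they would share 241. Both contrasts use the same estimate of each gene's spread, so the lists are not independent. In the same direction 1 gene rose in both and 1 fell in both, where independent lists would share 114 and 216.

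The antibody arm was also set against untreated tumours of days 3, 5 and 7, to see what differed when CTLs were given with the block. Some genes of T cells and of class II presentation rose. Of the T cell list 2 of 22 rose (6 adjusted over the list alone; adjusted p = 0.240 with an estimated correlation), with a median of 0.61 and 7 members below 0. Of the cytotoxic list 1 of 13 rose (9 adjusted over the list alone; adjusted p = 0.108 with an estimated correlation), with medians of 3.05, 2.69 and 0.16 on days 3, 5 and 7. Over the 3 days the median was 1.80, or 1.17 with dim members at their bound. Cd3d rose by 4.28 ± 0.53 (SE, n = 3 days; limma, adjusted p = 0.0362) and Nkg7, a protein of cytotoxic granules, by 2.94 ± 0.37. Cd8a was at least 4.81-fold, the chemokine Xcl1 at least 3.59-fold and C5ar1 at least 5.47-fold higher. Of the class II genes 4 of 10 rose (9 adjusted over the list alone; adjusted p = 0.0520 with an estimated correlation), H2-Ab1 (1.68), Cd74 (1.52), H2-Aa (1.51) and H2-Eb1 (1.44). No member of the interferon gamma list passed in limma (0 adjusted over the list alone), with a median of 0.51, or 0.38 with dim members at their bound. Its medians were 1.20, 0.09 and -0.14 on days 3, 5 and 7, and its camera call as higher was lost (adjusted p = 0.571 with an estimated correlation). Of the class I list 19 of 22 members were above 0, with a median of 0.49 (6 higher adjusted over the list alone; adjusted p = 0.260 with an estimated correlation). The endothelial list had a median of -0.57 (1 lower adjusted over the list alone; adjusted p = 0.289 with an estimated correlation), with -0.32, -0.00 and -1.11 on days 3, 5 and 7. The fibroblast list also had -0.57, with 16 of 18 members below 0 (3 lower adjusted over the list alone; adjusted p = 0.240 with an estimated correlation). The G2/M median was 0.02, without a call. Ifng had 3.58 ± 0.56 (adjusted p = 0.0900), Gzmb 3.23 ± 0.77, Cxcl9 1.00 ± 0.72 and Mki67 -0.09 ± 0.14. In all 27 genes passed in limma, 26 higher and 1 lower, and 0 passed without the day term. An unadjusted p under the threshold was found for 1175 of 17031 genes, where chance alone would give a share of 0.05.

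The last comparison asked whether the control IgG changed what CTLs alone did. The interferon gamma list had a median of 0.15 between these arms, without a call. Cxcl9 had -0.44 ± 0.72 (SE, n = 3 days) and Cd8a -0.47 ± 0.28, and neither passed. Of the T cell list 20 of 22 members were below 0, with a median of -0.26. Calm4, a calmodulin-like gene, was at least 2.29-fold lower with IgG (limma, adjusted p = 0.00934). That value rests on 1 of its 2 probes, since the other was not well above background on any array. The probe was bright on the CTL arrays alone, also on day 1 (-3.74, against -6.33 untreated). These arrays share 1 position on the slide, so position and CTLs cannot be told apart for it. The only other gene to pass was 1 transcript without an ordinary symbol, also lower, and 3207 genes had an unadjusted p under the threshold. The preset camera test called 6 lists lower with IgG: the T cell and class I lists (adjusted p = 0.0436 for each), the latter with a median of -0.18, and the endothelial, fibroblast, class II and keratinocyte lists, with medians of -0.69, -0.66, -0.54 and -0.73. Adjusted over the list alone, 7 endothelial genes were lower and 1 higher, 8 fibroblast, 5 class II and 3 keratinocyte genes were lower, and 0 T cell and 0 class I genes passed. G1/S and G2/M lists, with medians of 0.34 and 0.35, were called higher with 0 members passing in limma over either list alone. These calls were lost (adjusted p = 0.534 for the endothelial, fibroblast and class II lists, 0.378 for keratinocyte, 0.789 for T cell, class I and G1/S and 0.706 for G2/M genes, all with an estimated correlation). Mice of the IgG arm gave 3 tumours per array and those of the CTL arm 4, on the same slides.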

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

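The tests of the tumour cell share, of the dependence on interferon gamma, of dilution and of endothelial cell number were chosen only after the results were seen; the scaling tests and the splits of the samples were chosen before. For the endothelial cell number the bound was set, and then altered, with its count already known, so no verdict is drawn from it.

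Among the untreated arrays, day 7 stood apart in 4 measures, by the gap to its nearest neighbour over the range of the 4 arrays. Its median signal was 34.0, against 41.8 and 43.2 at the nearest and farthest of the others, a ratio of 0.850. Its 75th percentile was 303, against 470 and 495 (0.871), and its place on the second principal component, which held 11.5% of the variance, was -51.9, against 5.45 and 10.7 (0.916). Its mean level of the B cell list was -2.95, against -3.54 and -3.64 (0.845). Among the CTL arrays, day 5 had 48.9% of spots well above background, against 55.3% and 56.5% (0.840). In all 76 groups of 4 arrays were examined and 5 such gaps were found, which is near the share of about 1 in 20 that chance gives. The median and the 75th percentile of the signal are related measures. Days are not replicates, so a single array cannot be told from its day.

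The CTL effect differed between days 3, 5 and 7 and day 1 for 173 genes, by a test of the difference itself. H2-Aa differed by 4.96 ± 0.32 (adjusted p = 0.000925). Cd8a had a fitted difference of 5.15 ± 0.56 (adjusted p = 0.00871), but it was below the background limit on all untreated arrays, so the size is not measured, and it no longer passed with its probes averaged. Both were higher with CTLs on each of days 3, 5 and 7. Day 1 is 1 pair of arrays.

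G2/M genes were lower with CTLs on days 3, 5 and 7, with medians of -0.99, -1.19 and -0.42. A lower share of tumour cell RNA would lower melanocyte genes alike if their expression per tumour cell was unchanged, which was not measured. The melanocyte median lay above the G2/M median on each day, by at least 0.58 with an SD of 0.44. Melanocyte members ranged from -1.38 to 1.88 on day 3, so the median alone does not exclude a lower share. Against scaling as the cause, the G2/M median relative to all genes was -0.74 and stayed at -0.69 with quantile normalization and -0.65 with normexp. With anti-interferon gamma the G2/M median was higher than with IgG on each day, at its lowest 0.19, but its percentile of 98.6 among matched random lists decides nothing, since these ignore the correlation between the genes and placed the day 1 median of 0.04 with CTLs at 99.7. Over the list alone 0 members passed in limma in the fit of all arrays and 6 without day 1, and the list's call was lost in both (adjusted p = 0.408 and 0.360 with an estimated correlation). The antibody arm had a median of 0.02 against untreated tumours and IgG stood 0.35 above CTLs alone, so a dependence on interferon gamma may play a part but was not decided, and stays open, as do fewer cycling cells of any type and array position, which follows the arm.

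Endothelial medians with CTLs were -0.63, -0.21 and -0.92 on days 3, 5 and 7, of which day 5 lay at percentile 13.3 of matched random lists; camera made no call (adjusted p = 0.0596, and 0.0767 without day 1), and with the antibody they stood 0.83, 0.78 and 0.67 above IgG. Against untreated tumours the antibody arm was at -0.32, -0.00 and -1.11 on these days, where untreated day 7 is the array that stood apart, fibroblast genes were as low over the 3 days (-0.57 for each list), and IgG was at -0.69 against CTLs alone, so whether the block restores these genes is left open. Dilution by leukocyte RNA would lower fibroblast and melanocyte genes alike if their expression per cell was unchanged, which was not measured. Both medians lay above the endothelial median on each day, by at least 0.42 with an SD of 0.36. The rise with the antibody relative to all genes was 0.81, and 0.81 with quantile normalization, but 0.38 with normexp and quantile normalization. The planned test of scaling counted a loss under either, so it came out on the side of scaling. Quantile normalization alone left the rise in place, which argues against scaling as such, while background correction may account for part of it. Of the 16 markers 11 were lower with CTLs in the fit without day 1, of which 6 passed the threshold, and none of the other 5 passed. Fewer endothelial cells, lower expression per cell, an effect of the IgG and background correction stay open.

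Other splits of the 8 untreated and CTL arrays were counted for the number of genes. Of 35 splits, 2 gave at least as many genes as the real one (1837), and 1 of these is the real split itself. The other gave 6215 genes and set both day 1 arrays with the untreated arrays of days 3 and 5 against the rest. It thus parted the arrays by treatment on days 3 and 5, while on days 1 and 7 both arrays shared a group. By the rule fixed beforehand, a share of at least 0.05 of the splits, the count of 2 in 35 came out on the side of chance. But the split with 6215 genes carries the treatment labels of days 3 and 5, so this count cannot decide for or against chance. The remaining splits gave 2 genes or fewer. Among the 8 splits that part every day's pair, only the real one (1) gave as many, and the highest other gave 1 gene, but 8 splits are too few for a share under 0.05. The same holds for the 10 splits of each comparison of 3 arrays with 3, where the real and the highest other count were 5363 and 1 for CTL without day 1, 2 and 0 for the antibody, 2136 and 0 for the antibody without day 1, 2 and 0 for IgG, and 27 and 1 for the antibody against untreated tumours.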

How the results depend on the processing

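The alternatives to the fits without day 1 were chosen only after the data were seen; the others were planned. CTL versus untreated (1837 genes) gave 1612 genes with quantile normalization, 2350 with normexp and 1595 with the authors' values, of which 1500, 1645 and 1587 were shared. It gave 3333 with trend and robust, 6 without the filter, 5 without the day term and 1 with only the arrays of the 2 arms. Without day 1 it gave 5363, without day 3, 5 or 7 each 0, and without single arrays 3 to 5363. For anti-IFNg versus IgG (2 genes) the counts were 0 with quantile normalization or no filter, 663 with normexp, 1022 with the filter on all 14 arrays, 1240 with trend and robust, 911 with only the 2 arms, 4 without the day term, 2136 without day 1, 0 without day 3, 5 or 7, and 0 to 2 without single arrays. Leaving out day 1 did not alter the antibody log2 differences, since day 1 has no array of these arms. The shift from 2 to 2136 genes therefore came through the shared estimate of the spread. The median residual SD was lower without day 1, both over all genes and over the interferon gamma list. For the other shifts here and those that follow the cause was not tested, except where stated. IgG with CTL versus CTL alone (2) gave 1 with normexp, 0 with the filter on all 14 arrays, 4 without the day term and 0 to 2 without a day. For anti-IFNg with CTL versus untreated (27) the fit gave 9 with normexp, 10 without the filter, 13 with the filter on all 14 arrays, 0 without the day term and 1 to 18 without a day. The CTL effect on days 3 to 7 minus day 1 (173) gave 156 to 257 under the other scalings and filters, but 5, 4 and 295 without day 3, 5 and 7. CTL versus untreated, without day 1 (5363), gave 836 with only the 2 arms, and 1098, 660 and 5111 with day 3, 5 or 7 also left out; anti-IFNg versus IgG, without day 1 (2136), gave 911, 398, 50 and 1376. The overlap of genes raised by CTL and lowered by anti-IFNg (0) became 249 with normexp, 382 with the filter on all 14 arrays and 0 to 898 without a day. The slope stayed at 0 in limma under all 5 alternatives. Of the 21 lists called in each main comparison, 0 and 0 were called with an estimated correlation. Cd8b1 reversed with the antibody without day 1, from 0.85 to -0.46 with its probes averaged, since its 2 probes disagree, and to -1.47 with normexp, where the cause was not tested. Of the other comparisons of named genes with their alternatives 3003 kept their side of the threshold, 77 fell short of it and 70 passed it; of those of lists 411 kept it, 68 fell short and 7 passed. Of the list medians per day, 12 moved by over 1 SD with quantile normalization and 177 by less, 74 and 115 with normexp, and 0 and 189 with the authors' values, whose scaling is the same. Scaling shifted the median of all genes by at most 0.044. For dim genes, signal over background limits the size of a change.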

Other observations

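All the genes in this part were chosen after their values were seen, and no explanation was tested for them. Calm4 was well above background on all 4 CTL arrays with 1 of its 2 probes, and on none of the other 10 arrays. For Tnfrsf14, 1 of 2 probes was well above background on 4 of 4 CTL arrays and 3 of 3 IgG arrays, and on no untreated array and no array with anti-interferon gamma. The other probe passed that limit on only 1 CTL array and 2 IgG arrays. On day 1 it stood at -5.63 with CTLs and -5.33 without, and on day 7 at -4.35 and -4.64. Of the 2 probes of Cd8b1, on day 3 one stood at 2.06 with CTLs and -3.95 without, and the other at -0.99 and 0.00. The erythroid list had medians of -1.46, 0.05, -2.95 and -3.92 on days 1, 3, 5 and 7 with CTLs. With the antibody against IgG its median was 1.03, with 6 of 7 members above 0, and camera made no call (adjusted p = 0.277). The neutrophil list stood 1.65 higher with IgG than with CTLs alone on day 7, each on 1 array. The same IgG array is the one against which the antibody array of day 7 was set.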
